A study of Homo sapiens with 6 samples.

How the data were processed

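RNA from 6 samples of transfected LNCaP cells was measured on one-colour Agilent human gene expression arrays, with 2 samples each of control (empty vector), wild-type ERG and mutant ERG (K362A). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the cells were transfected, selected with G418 and kept in medium with serum and G418; total RNA was treated with DNase, labelled with a cyanine dye and hybridised. Per the file headers, the deposited scanner files hold the intensity of each spot, extracted with grids built on hg19, and the processed intensity column is background-subtracted and detrended within each array, without normalization between arrays. The submitters' processing notes name Agilent Feature Extraction 10.7 and limma, with no settings. The series matrix deposited by the authors holds log2 values of the same arrays; its 6 column medians lay between 6.51 and 6.52, its values correlated with the log2 processed intensity of the same array at r = 0.953 to 0.962, and differences between arrays at 0.615 to 0.716. Its rise with the scanner intensity settles its direction, while its background correction and its normalization stay unknown.

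Each array had 58717 non-control spots for 50599 probes, 902 of which were printed in 10 spots each and averaged. Between 268 and 353 spots per array carried an outlier flag and were left out, which removed 27 probes, and 0 spots were saturated. The 75th percentile of the processed intensity was 590 and 419 for wild-type ERG replicates 1 and 2, 722 and 510 for the mutant, and 832 and 790 for control. Probes well above background numbered 32434 (64.1%) and 28996 (57.3%) with wild-type ERG, 27694 (54.7%) and 28669 (56.7%) with the mutant, and 29880 (59.1%) and 28027 (55.4%) in control. No per-array depth exists beyond these values, and the number of arrays limits the precision.

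The processed intensity was log2 transformed and each array's 75th percentile was subtracted. Probes well above background on both arrays of at least 1 group were kept (29751), and per gene the probe with the highest mean over the 6 arrays was tested (22231 genes or unnamed transcripts). Probes were named through the accession in the files matched to a RefSeq gene table of assembly GRCh38.p14 (28242 probes), through the symbol (2618) or a synonym (583), and otherwise kept the file's own name (19156). Coordinates are those of the probes in the files (hg19). No annotation of that build was used, so exon, intron or UTR positions of probes are not given. Of called genes with several probes, 74 of 421 with wild-type ERG, 5 of 60 with the mutant and 4 of 54 between the 2 forms had a probe of opposite sign.

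The 3 comparisons were contrasts of one limma fit over all 6 arrays (limma 3.58.1 in R 4.3.3, lmFit and eBayes, two-sided, 3 residual degrees of freedom plus 1.93 prior degrees of freedom) with Benjamini-Hochberg adjustment at 0.05 and no covariate. Values after ± are standard errors from that fit. Where the tested probe was well above background on no array of a group, its fold is given as a bound, the brighter group's mean against, per array, the higher of the probe's own signal and the lowest signal well above background. The tested probe was well above background on 1 of 2 arrays for SNORD66 and ICAM2 in control, OASL, KRT17, PDGFRB, CAV1 and EPHX4 with wild-type ERG, and EPHX4 and FST with the mutant. Lists of genes (30 lists, at least 5 tested members each) were tested with camera at a preset correlation of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation, under which 0 of the 22 list calls held. Of these lists, 2 are left out of the text, so the text does not describe every list that camera called, while the totals count them. Camera compares a list with the other genes, so its calls are relative to the shift of all genes.

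Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule took 3 fixed genes, of which ERG and EZH2 are reported, the 8 largest increases and decreases with separate groups and an informative symbol per comparison, up to 3 called members of each list by size (2 by size, as values, where camera called a list with no called member), and the 8 genes shared by both comparisons with control by their smaller change. Of the called genes, 503, 56 and 69 had only an identifier as a name and could not be named. Alternatives were normexp background correction (offset 50), quantile and median scaling, no or a stricter background filter, other handling of several probes per gene, slide as a fixed block, as a random block (statmod 1.5.0, consensus correlation 0.632) and slide 1 alone, the replicate number as a block, only the groups compared, eBayes with trend, other thresholds, the authors' matrix, and leaving out each array. Simulations of unchanged groups that keep each gene's fitted slide difference were added after the data were examined, and these differences include their own estimation noise. Tables were read with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.

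The fit was tested on simulated data with the 22231 genes and 200 of them changed (5 simulations). In wild-type ERG against control it recovered 1.82%, 60.3% and 89.0% of genes changed by 1, 2 and 3 log2 units, with 5.60% false calls. In mutant ERG against control it recovered 1.21%, 58.5% and 84.5%, with 4.36% false calls, and between the 2 forms 0.606%, 56.4% and 86.6%, with 5.69% false calls. Camera found a list shifted by 0.5 in 100% of 20 simulations, and other lists had p under 0.05 in 3.45%. The simulated genes were independent, with the same spread in all groups and no slide difference. These rates therefore need not hold for the real arrays, whose replicates differed more with ERG than in control.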

Results

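The series measured RNA levels in LNCaP cells, an established human prostate cancer line. Cells had been stably transfected with wild-type ERG, an ETS family transcription factor, with the ERG mutant K362A, in which lysine at protein position 362 is replaced by alanine, or with an empty vector. Each of the 3 groups had 2 arrays, described in the series as separate cell lines. No label says whether each line is a separate transfection, a clone or a pool, so p-values measure only the spread between these samples, which may be technical or clonal. Each of the 6 one-colour arrays held 58717 spots for 50599 probes. Between 27694 probes (54.7%, mutant replicate 1) and 32434 probes (64.1%, wild-type replicate 1) were well above background, and 22231 genes or unnamed transcripts were tested. Slide 1 held both control arrays and replicate 1 of each ERG group, and slide 2 held replicate 2 of each ERG group. The median absolute log2 difference between replicates was 0.10 in control, 0.29 in wild-type ERG and 0.41 in mutant ERG. The number of arrays limits the precision of every value below.

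The first question was whether the ERG transcript itself was raised by the transfections. The ERG probe (chromosome 21, positions 39774486 to 39774545, hg19) was not well above background in control cells. Its signal was at least 10.72-fold higher with wild-type ERG (limma adjusted p = 0.00978, n = 2 per group). With the mutant it was at least 109-fold higher (adjusted p = 0.016, n = 2 per group). These and all later bounds hold for the Feature Extraction background correction only. With normexp, every called gene that was named for its own comparison and had a bound had a fitted fold below it. The bounds of ALDH1A1 and IGFBP5 with wild-type ERG, given further below, were not part of that check. The mutant cells held more of this transcript than the wild-type cells, by 10.1-fold (wild-type minus mutant log2 fold change -3.34 ± 0.39 SE, adjusted p = 0.0433). The ERG signal was lower with wild-type ERG than with the mutant on both slides. The files do not say whether this probe lies in the transfected cDNA, and protein was not measured on these arrays. EZH2, the methyltransferase subunit of Polycomb repressive complex 2, gave 0.06 ± 0.15 and 0.08 ± 0.15 in the comparisons with control, neither past the threshold.

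**Figure D1:**
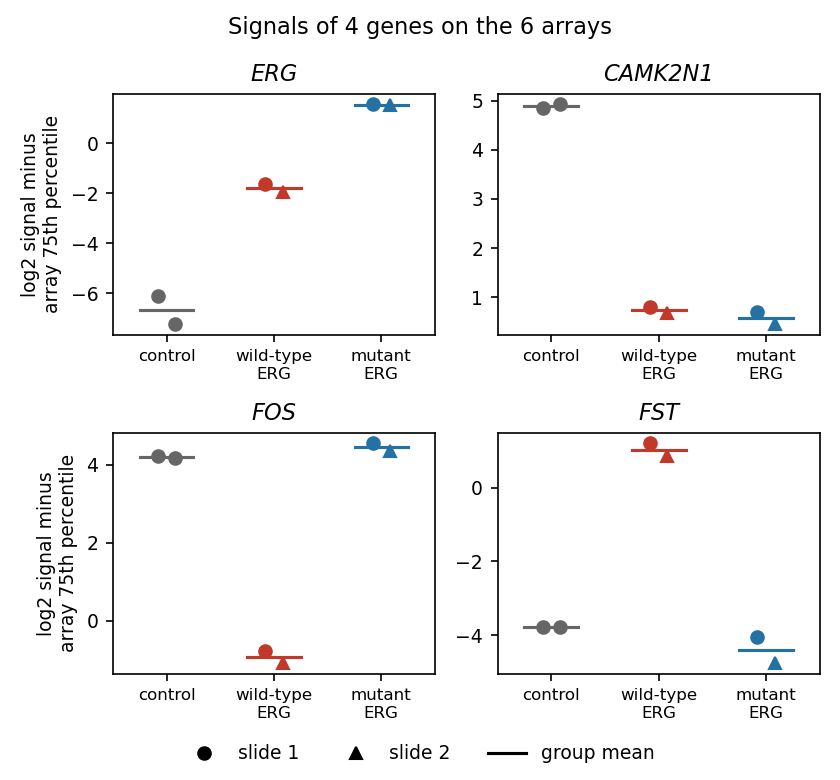
Normalised log2 signal (array 75th percentile = 0, vertical axis) of ERG, CAMK2N1, FOS and FST on each array of the control, wild-type ERG and mutant ERG groups (horizontal axis); circles are slide 1 arrays, triangles slide 2 arrays, and lines group means (n = 2). ERG was highest in the mutant group, FOS was lowest and FST highest in the wild-type group, and CAMK2N1 was lowered in both ERG groups.

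The comparison of wild-type ERG with control asked which transcripts differed in cells that overexpress the intact factor. The largest increases were in THSD7A, which encodes a membrane protein (chromosome 7, positions 11414465 to 11414524; at least 43.5-fold), and ADRA2A, the alpha-2A adrenergic receptor (45.6-fold, log2 5.51 ± 0.15). PAGE1, a cancer-testis antigen, rose 42.5-fold (5.41 ± 0.28). RETN, which encodes the hormone resistin, rose at least 21.6-fold, the kallikrein gene KLK8 at least 14.0-fold, NINJ2, an adhesion molecule gene, at least 13.6-fold and the small nucleolar RNA gene SNORD66 31.4-fold (4.97 ± 0.91). The largest decrease was in the histone variant gene H2AJ (chromosome 12, positions 14927815 to 14927874), which fell 882-fold (-9.78 ± 0.15). Its 2 probes had the same sign here, but not between the 2 ERG forms. KCNJ3, a potassium channel subunit, fell 43.3-fold (-5.44 ± 0.18), the tetraspanin TSPAN12 at least 21.4-fold, FGF13 at least 15.9-fold, SLITRK3 at least 10.9-fold and the sialyltransferase gene ST8SIA4 at least 8.67-fold. TSPY3 and TSPY2, probed on chromosome Y, gave -5.61 ± 0.23 and -5.14 ± 0.17. They are near-identical members of a multicopy testis family that 1 probe may not separate. All these calls had adjusted p-values between 0.000458 (H2AJ) and 0.0426 (SNORD66).

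In all, 1869 of 22231 genes passed adjusted p of 0.05 in this comparison (limma), 1063 higher and 806 lower. With slide as a block the count was 3130 (1836 higher and 1294 lower), of which 1715 were shared. The split depended on the scaling: quantile normalization gave 811 higher and 1093 lower, median scaling 1068 and 2854, and the authors' matrix 1179 and 1392. The median absolute log2 fold change of the called genes was 1.496, and 0.957 with normexp. The median log2 fold change of all genes was 0.14 with the 75th percentile, 0.003 with quantile normalization and -0.51 with median scaling. Leaving out wild-type replicate 1 or 2 left 0 genes past the limma threshold (6043 and 4059 at unadjusted p under 0.05), and leaving out control replicate 1 or 2 left 1 gene each; leaving out either mutant array gave 4505.

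**Figure D2:**
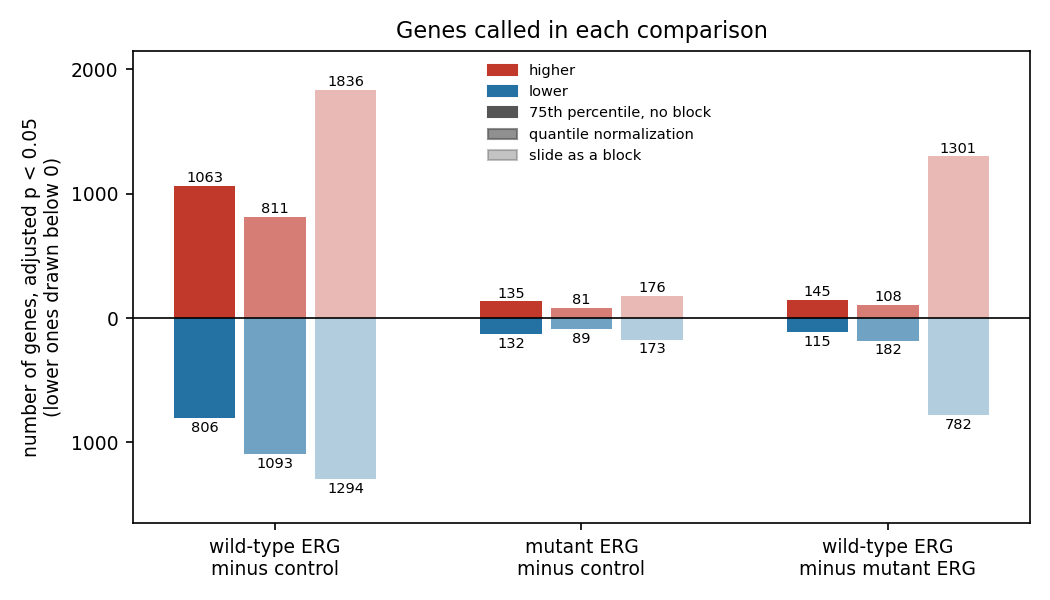
Number of genes past adjusted p of 0.05 in each of the 3 comparisons (bars from 0, higher and lower genes apart) under 75th percentile scaling, quantile normalization, and 75th percentile scaling with slide as a block. Wild-type ERG against control gave 1869, 1904 and 3130 genes, and mutant ERG against control 267, 170 and 349.

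Luminal and basal prostate markers moved in single members with wild-type ERG. Of 14 luminal prostate markers, 3 rose, led by TRPM8 (1.80 ± 0.35) and NPY (1.25 ± 0.15), and 0 fell, 7 rising adjusted over the list alone, with camera adjusted p = 0.26. Of 10 basal prostate markers, KRT14 (-2.28 ± 0.22) and KRT17 (-1.92 ± 0.30) fell, 4 adjusted over the list alone, with camera adjusted p = 0.0888.

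Interferon-stimulated genes, mitosis genes and immediate early genes were lower with wild-type ERG. Of 28 interferon genes, 9 fell and 0 rose (17 fell adjusted over the list alone), among them OASL (-3.16 ± 0.32), IFIT1 (-2.75 ± 0.25) and DDX60 (-2.10 ± 0.29). Their median was -0.90 (-0.87 with slide as a block, -0.85 within slide 1; camera adjusted p = 5.04e-10, and adjusted p = 0.52 with an estimated correlation). Of 20 mitosis genes, 6 fell and 0 rose (13 adjusted over the list alone), led by the kinase gene PLK1 (-1.60 ± 0.24), the centromere histone gene CENPA (-1.58 ± 0.29) and BUB1 (-1.30 ± 0.24). The mitosis median was -0.79 (-0.70 with the block, -0.69 within slide 1; camera adjusted p = 1.34e-07, adjusted p = 0.74 with an estimated correlation). Of 13 immediate early genes, 6 fell and 0 rose, also 6 adjusted over the list alone. FOS fell 34.8-fold (chromosome 14, positions 75748214 to 75748273; -5.12 ± 0.18), EGR1 15.8-fold (-3.98 ± 0.19) and FOSB 6.45-fold (-2.69 ± 0.14). The immediate early median was -0.35 (-0.35 with the block, -0.26 within slide 1) and its mean -1.29 (camera adjusted p = 2.01e-05, adjusted p = 0.52 with an estimated correlation).

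Stress response and lipid synthesis lists were also lower with wild-type ERG. Of 21 ATF4 and unfolded protein response genes, 5 fell and 0 rose (9 adjusted over the list alone), among them CHAC1 (-2.08 ± 0.17), ATF3 (-1.89 ± 0.20, the same sign at 3 of its 4 probes) and CTH (-1.36 ± 0.14). That median was -0.59 (-0.64 with the block, -0.57 within slide 1; camera adjusted p = 6e-06, adjusted p = 0.61 with an estimated correlation). Of 14 NF-kB inflammatory genes, 4 fell and 0 rose (6 adjusted over the list alone). The chemokine gene CXCL2 fell at least 16.8-fold, CCL20 12.3-fold (-3.62 ± 0.31) and BIRC3 4.70-fold (-2.23 ± 0.16). The median was -0.65 (-0.77 with the block, -0.83 within slide 1; camera adjusted p = 0.000276, adjusted p = 0.52 with an estimated correlation). Of 19 cholesterol synthesis genes, MVD fell (-1.11 ± 0.15) and SC5D rose (1.09 ± 0.20), with 3 falling and 1 rising adjusted over the list alone. The median was -0.48 (-0.32 with the block, -0.29 within slide 1; camera adjusted p = 0.00201, adjusted p = 0.77 with an estimated correlation). Of 12 fatty acid synthesis genes, ELOVL6 fell (-1.57 ± 0.23), 5 adjusted over the list alone. The median was -0.52 (-0.34 with the block and within slide 1; camera adjusted p = 0.0493, adjusted p = 0.77 with an estimated correlation), and the list was not past the threshold with slide as a block.

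Lists of genes described as ERG targets were not called by camera. Of 13 targets from invasion models, ADAMTS1 (2.93 ± 0.16), VIM (2.29 ± 0.23) and CXCR4 (1.66 ± 0.18) rose and 0 fell, while adjusted over the list alone 5 rose and 5 fell (camera adjusted p = 0.745). Of 15 genes associated with ERG in prostate tumours, 1 rose, also 1 adjusted over the list alone, ARHGDIB (2.42 ± 0.18; camera adjusted p = 0.926). Of 22 ETS family genes, ERG and FEV (4.33 ± 0.20) rose and 2 fell, ELF3 (-1.23 ± 0.17) being the larger, with 3 rising and 5 falling adjusted over the list alone (camera adjusted p = 0.997). Of 11 genes repressed by EZH2 in prostate cancer, IGFBP3 rose 11.5-fold (3.53 ± 0.21), 1 of 11 also adjusted over the list alone (camera adjusted p = 0.925). No tested member of 11 Polycomb repressive complex 2 subunits passed the threshold, 0 adjusted over the list alone (camera adjusted p = 0.663).

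The comparison of the K362A mutant with control asked which transcripts differed in cells that overexpress the altered factor. Apart from ERG, large increases were in ALDH1A1, a retinaldehyde dehydrogenase whose tested probe was not well above background in control (at least 11.5-fold, adjusted p = 0.016), ARAP3, a GTPase-activating protein (12.4-fold, 3.63 ± 0.21), and SGCE, a sarcoglycan (12.1-fold, 3.60 ± 0.25). PNLIP, the pancreatic lipase gene, rose at least 9.44-fold, IGFBP5 at least 5.37-fold, the antisense transcript gene GATA3-AS1 at least 3.96-fold and THSD7A at least 3.30-fold. The largest decreases were in CAMK2N1, an inhibitor of calmodulin-dependent kinase II (chromosome 1, positions 20809401 to 20809460; 19.8-fold, -4.31 ± 0.16), EPHX4 (17.6-fold, -4.14 ± 0.36), TLL1, a metalloprotease (17.3-fold, -4.12 ± 0.19), and TSPAN12 (9.79-fold, -3.29 ± 0.24). SLC44A5 fell at least 5.34-fold. PAX2 (at least 3.81-fold), NTS, which encodes neurotensin (at least 2.99-fold), and OPRK1, the kappa opioid receptor (at least 3.47-fold), fell too, and these 3 were not past the threshold with slide as a block. Adjusted p-values of the calls named here lay between 0.016 and 0.0462.

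In all, 267 of 22231 genes passed the limma threshold with the mutant, 135 higher and 132 lower. With slide as a block 349 passed (176 higher and 173 lower, 211 shared), and quantile normalization gave 170 (81 higher and 89 lower). Median scaling gave 485 (203 higher and 282 lower). No background filter, only the groups compared and the replicate number as a block each gave 0. The median log2 fold change of all genes was 0.01. Within slide 1 alone, with 1 residual degree of freedom, 0 genes passed (5970 at unadjusted p under 0.05). Leaving out mutant replicate 1 gave 168 genes, 94 of them among the 267, and leaving out any 1 of the other 5 arrays gave 0, with 2879 at unadjusted p under 0.05 without either wild-type array.

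Interferon-stimulated genes were lower with the mutant as a list, with members in both directions. Of 28 interferon genes, BST2, which encodes tetherin, rose 5.29-fold (2.40 ± 0.14) and IFI6 fell 3.09-fold (-1.63 ± 0.17), and 2 rose and 7 fell adjusted over the list alone. Their median was -0.72 (-0.51 with the block, -0.64 within slide 1; camera adjusted p = 7.46e-07, adjusted p = 0.49 with an estimated correlation).

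Antigen presentation, NF-kB, immediate early, luminal and cholesterol lists passed camera with the mutant too, by smaller shifts than the interferon list. Of 14 antigen presentation genes, 0 passed singly and 2 fell adjusted over the list alone; PSMB9 had -1.04 ± 0.14 (adjusted p = 0.0562), PSMB8 was not well above background with the mutant, and the list median was -0.47 (-0.51 with the block, -0.50 within slide 1; camera adjusted p = 0.00799, adjusted p = 0.49 with an estimated correlation). Of 14 NF-kB inflammatory genes, 0 passed singly and 3 fell adjusted over the list alone; BIRC3 had -1.19 ± 0.16 (adjusted p = 0.0566) and NFKB1 -1.16 ± 0.39, with a median of -0.33 (-0.38 with the block, -0.27 within slide 1; camera adjusted p = 0.0158, adjusted p = 0.49 with an estimated correlation). Of 13 immediate early genes, FOSB rose 2.19-fold (1.13 ± 0.14), also 1 adjusted over the list alone, and the median was 0.25 (0.36 with the block, 0.30 within slide 1; camera adjusted p = 0.0252, adjusted p = 0.49 with an estimated correlation). Of 14 luminal markers, 0 passed singly and 3 rose adjusted over the list alone, with values of 0.96 ± 0.17 for SLC45A3 and 0.76 ± 0.15 for NPY. The luminal median was 0.25 (0.26 with the block, 0.25 within slide 1; camera adjusted p = 0.0464, adjusted p = 0.74 with an estimated correlation). Of 19 cholesterol genes, 0 passed, also 0 adjusted over the list alone, with -1.05 ± 0.33 for STARD4 and -0.50 ± 0.34 for MSMO1. The cholesterol median was -0.28 (-0.14 with the block, -0.13 within slide 1; camera adjusted p = 0.0207, adjusted p = 0.74 with an estimated correlation), and that list was not past the threshold with slide as a block.

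Among lists that camera did not call with the mutant (adjusted p from 0.0628 for basal markers to 0.923), single members passed. CXCR4 (2.07 ± 0.18) and ADAMTS1 (1.24 ± 0.16) rose and PLAUR fell (-1.21 ± 0.14) among 13 invasion model targets, with 3 rising and 2 falling adjusted over the list alone, and ADAMTS1 was not past the threshold with slide as a block. FEV rose 5.59-fold (2.48 ± 0.20), so 2 of 22 ETS family genes rose, ERG being the other, and 2 adjusted over the list alone. The basal keratin genes KRT14 (-2.63 ± 0.22) and KRT17 (at least 5.21-fold lower, not past the threshold with slide as a block) fell, 2 of 10 basal markers and 2 adjusted over the list alone. The 20 mitosis genes had a median of 0.04 with the mutant (0.24 with slide as a block, 0.26 within slide 1), and 0 of them passed, 0 adjusted over the list alone (camera adjusted p = 0.515). With slide as a block camera called this list, higher with the mutant (adjusted p = 0.00513 at the preset correlation). Without the block, an estimated correlation gave camera adjusted p = 0.863.

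**Figure D3:**
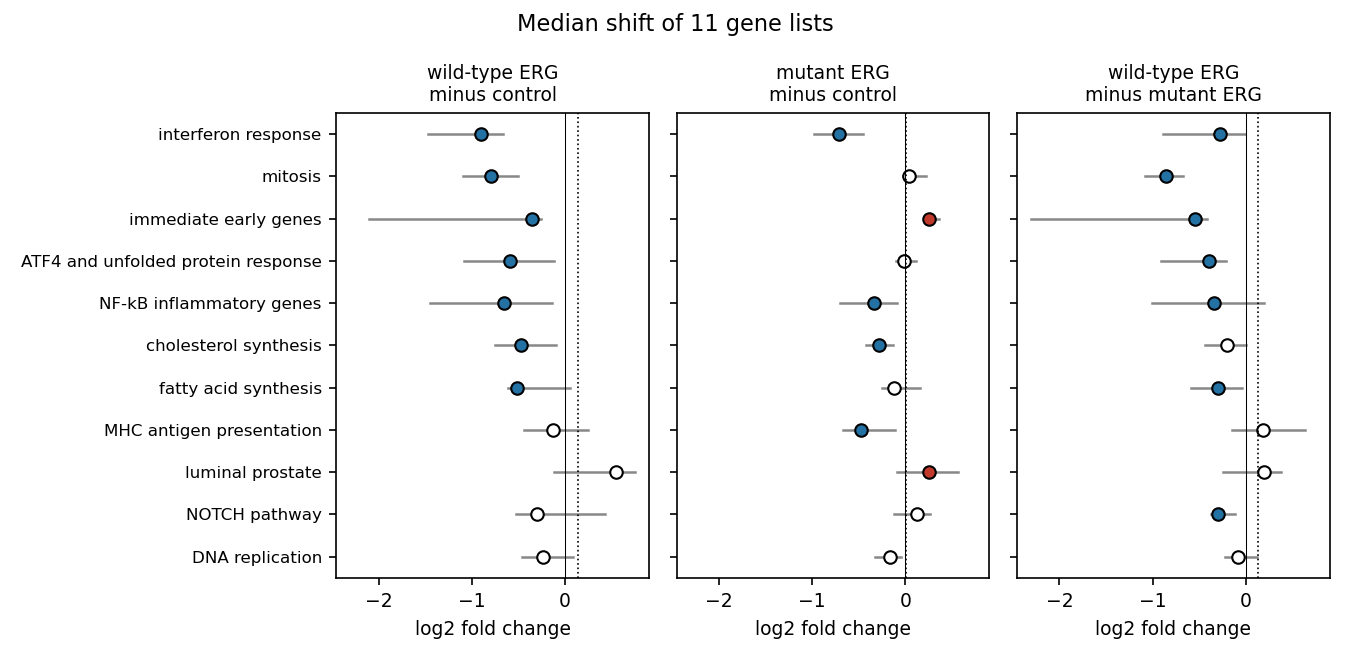
Median log2 fold change (horizontal axis) of 11 gene lists in the 3 comparisons; grey bars are the quartiles of the members, filled red or blue points have camera adjusted p under 0.05 with the preset correlation, and dotted lines are medians of all tested genes. Interferon genes lay at -0.90 with wild-type ERG and -0.72 with the mutant, and mitosis genes at -0.79 and 0.04.

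The comparison of wild-type ERG with the mutant tested directly whether cells with the 2 forms differed. These cells also differed in ERG transcript (log2 -3.34 ± 0.39), so form and amount of ERG cannot be separated. FST, which encodes the activin-binding protein follistatin, was 43.3-fold higher with wild-type ERG (chromosome 5, positions 52780837 to 52780896; 5.44 ± 0.29), and PAGE1 30.5-fold higher (4.93 ± 0.28). NINJ2 was at least 11.6-fold, the microRNA host gene MIR124-1HG at least 10.3-fold, LY86 13.2-fold (3.72 ± 0.36) and THSD7A 13.2-fold higher (3.72 ± 0.29). The cancer-testis gene CT83 was at least 2.91-fold and PLCXD3 at least 2.71-fold higher. In the other direction, H2AJ was 166-fold lower with wild-type ERG (-7.37 ± 0.15), although the other of its 2 probes had the opposite sign. FOS was 41.4-fold lower (-5.37 ± 0.18), EGR1 20.3-fold lower (-4.34 ± 0.19), and HES1, a repressor downstream of NOTCH, 19.5-fold lower (-4.29 ± 0.28). MAGEC2, of the same class as CT83, was at least 13.7-fold lower, CXCL2 at least 10.9-fold, STON1-GTF2A1L at least 4.93-fold and the relaxin gene RLN1 at least 3.97-fold. Adjusted p-values of these calls lay between 0.00185 and 0.0435.

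In all, 260 of 22231 genes passed the limma threshold, 145 higher and 115 lower with wild-type ERG. With slide as a block the count was 2083 (1301 higher and 782 lower) and held all 260. Quantile normalization gave 108 higher and 182 lower, and median scaling 405 and 494. Normexp gave 136 genes (66 higher and 70 lower), the replicate number as a block 89, no background filter 2 and only the groups compared 1. The median of all genes was 0.13. Within slide 1 alone 0 genes passed with 1 residual degree of freedom (8770 at unadjusted p under 0.05). Leaving out mutant replicate 2 gave 1156 genes. Leaving out either wild-type array left 0 (3253 at unadjusted p under 0.05 without replicate 1), and leaving out mutant replicate 1 or either control array left 1.

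Mitosis and immediate early lists were called lower with wild-type ERG than with the mutant, at the preset correlation only. Each slide holds 1 array of each form, so slide as a block changes the tests but not the medians here. Of 20 mitosis genes, 0 passed over all genes and 18 were lower with wild-type ERG adjusted over the list alone; CENPA had -1.57 ± 0.29 (adjusted p = 0.0877) and AURKB -1.18 ± 0.20 (adjusted p = 0.0794), and both passed with slide as a block. The mitosis median was -0.86 (-0.94 within slide 1, -0.81 within slide 2; camera adjusted p = 1.82e-14, and adjusted p = 0.45 with an estimated correlation). Of 13 immediate early genes, 6 were lower and 0 higher (7 adjusted over the list alone), with FOSB at -3.82 ± 0.14. That median was -0.54 (-0.55 within slide 1, -0.92 within slide 2) and the mean -1.61 (camera adjusted p = 7.12e-11, adjusted p = 0.28 with an estimated correlation). Of 21 ATF4 and unfolded protein genes, CHAC1 (-2.07 ± 0.17) and ATF3 (-1.91 ± 0.20) were lower, 6 adjusted over the list alone. The median was -0.39 (-0.45 within slide 1, -0.34 within slide 2; camera adjusted p = 2.04e-09, adjusted p = 0.45 with an estimated correlation). Of 28 interferon genes, BST2 was lower (-2.48 ± 0.14), 6 adjusted over the list alone, with a median of -0.28 (-0.23 and -0.31 within slides 1 and 2; camera adjusted p = 1.91e-05, adjusted p = 0.45 with an estimated correlation).

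NOTCH, NF-kB and fatty acid lists were also lower with wild-type ERG than with the mutant. Of 13 NOTCH pathway genes, HES1 was lower, 2 adjusted over the list alone, and the median was -0.30 (-0.31 within each slide; camera adjusted p = 0.00392, adjusted p = 0.45 with an estimated correlation). Of 14 NF-kB genes, CXCL2 and CCL20 (-2.95 ± 0.31) were lower, and 5 were lower and 2 higher adjusted over the list alone. The NF-kB median was -0.35 (-0.60 and -0.51 within slides 1 and 2; camera adjusted p = 0.00407, adjusted p = 0.45 with an estimated correlation). Of 12 fatty acid genes, 0 passed, 0 adjusted over the list alone, with -0.999 ± 0.365 for ACSL1 and -0.84 ± 0.23 for ELOVL6, which both passed with slide as a block, and the median was -0.30 (-0.43 and -0.28 within slides 1 and 2; camera adjusted p = 0.00833, adjusted p = 0.88 with an estimated correlation). Single members of other lists were higher with wild-type ERG, among them ANXA1 (3.20 ± 0.25), IGFBP3 (2.73 ± 0.21), ARHGDIB (2.41 ± 0.18), FEV (1.85 ± 0.20), ADAMTS1 (1.68 ± 0.16) HLA-DMB (1.37 ± 0.14) and CAV1 (at least 1.65-fold, but -0.097 and not called in the authors' matrix), while LOX (-2.09 ± 0.18), DDC (-1.38 ± 0.15) and ADM (-1.26 ± 0.15) were lower.

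Genes called in both comparisons with control included ERG. CAMK2N1 fell in both (-4.15 ± 0.16 with wild-type ERG and -4.31 ± 0.16 with the mutant), as did EPHX4 (-3.82 ± 0.36 and -4.14 ± 0.36). ALDH1A1 rose in both (at least 16.6-fold and at least 11.5-fold), as did ARAP3 (3.79 ± 0.21 and 3.63 ± 0.21) and RBMS1, an RNA-binding protein gene (4.17 ± 0.15 and 3.30 ± 0.15). THSD7A rose at least 43.5-fold and at least 3.30-fold, and IGFBP5 at least 4.76-fold and at least 5.37-fold. In total 214 genes were called the same way in both, 110 higher and 104 lower, and 3 were called in opposite directions. Independent lists of these sizes would share 6.46 higher and 4.79 lower genes, and part of the excess over them may come from the shared controls, since 2 control arrays cannot be split. In 100 simulations of unchanged groups against the same controls, 0.01 genes were shared on average and 1 at most, and 0 were shared when each gene's fitted slide difference was kept in the simulated arrays. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.66, above the 0.50 simulated without a slide difference and below the 0.80 simulated with it. Their covariance was 0.371, against 0.069 simulated without and 0.124 with a slide difference, and 77.0% of genes had the same sign (66.6% simulated without it). With slide as a block 294 genes were shared (0 simulated), r was 0.50 (0.60 simulated) and the covariance 0.224 (0.046 simulated). The correlation therefore did not exceed that of unchanged groups with a slide difference, while the covariance did. Unchanged groups give a shared count near 0 by design. The simulated counts therefore cannot show how many calls the shared controls add when both groups differ from control. Every simulated array had the same spread per gene. The real replicates differed by a median of 0.10 in control, 0.29 with wild-type ERG and 0.41 with the mutant. The shared calls depend on the fit: 139 were shared with quantile normalization, 111 of them among the 214, 0 without the background filter and 0 with the replicate number as a block, and leaving out any 1 array but mutant replicate 1 left 0 calls with the mutant to share.

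**Figure D4:**
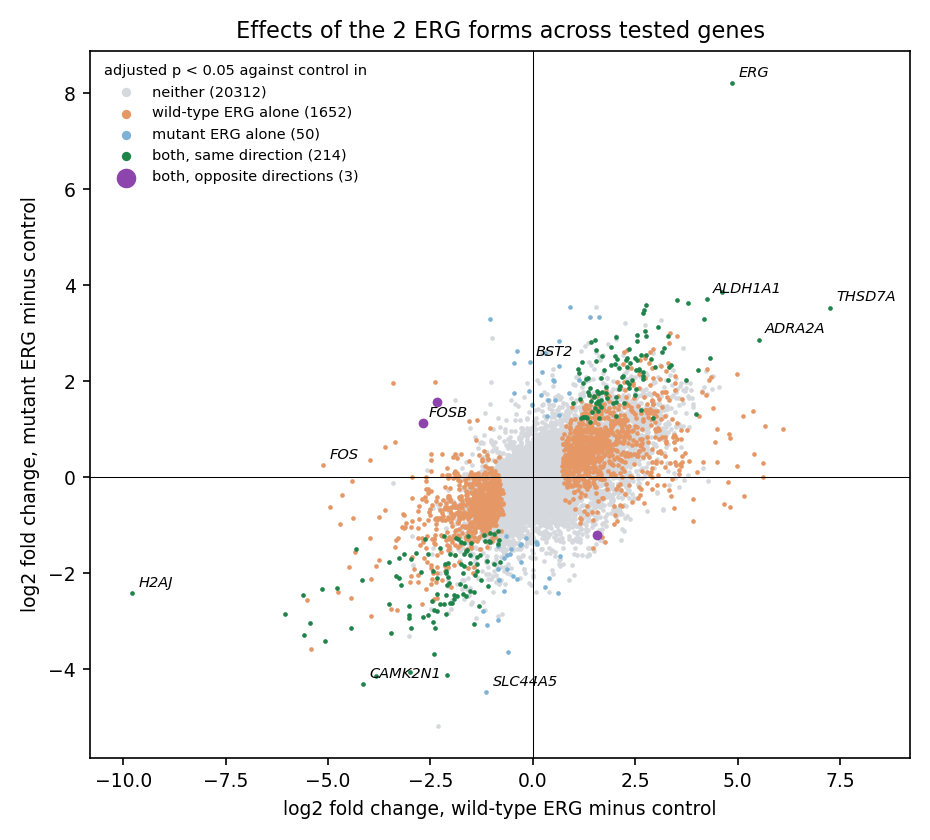
Log2 fold change against control with wild-type ERG (horizontal axis) and with mutant ERG (vertical axis), 1 point per tested gene, coloured by the comparison in which it passed adjusted p of 0.05. Of 1869 genes called with wild-type ERG and 267 with the mutant, 214 were called in both the same way and 3 in opposite directions.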

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

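Only the test of probe brightness was chosen before the values it measures were seen; all other tests here were chosen after. The shares of list members and the distance from control over all genes replaced earlier tests, which rested on list medians and on genes selected for differing between the groups, and the standard error was added to the test along chromosome 18 after its first result.

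Cells with wild-type and mutant ERG differed for 260 genes, ERG among them, in the test of the difference itself. Called in opposite directions against control were 3 genes. FOSB had -2.69 with wild-type ERG and 1.13 with the mutant (wild-type minus mutant -3.82 ± 0.14). PRXL2A, named after its values were seen, had -2.34 and 1.57 (-3.91 ± 0.17), and its 2 probes did not share their sign with wild-type ERG. An unnamed Ensembl transcript had 1.55 and -1.19 (2.75 ± 0.14).

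Genes of chromosome 18 had a lower median in both ERG groups than in control, with 55.7% of 334 genes below the median of all genes with wild-type ERG and 63.8% with the mutant. On chromosome 16 these shares were 60.1% and 62.2% of 961 genes, and the tests below were run for chromosome 18 only. The chromosome 18 median lay at -0.27 with wild-type ERG and -0.25 with the mutant, relative to all genes. It was nearer 0 with normexp (-0.15 and -0.14) and in the authors' matrix (-0.12 and -0.15). Among the 23 chromosomes examined, which left out Y, chromosome 16 was as low with wild-type ERG (-0.28) and less so with the mutant (-0.15). Chromosome 21 was highest (0.22 and 0.07). A difference between the slides is argued against by the ERG arrays that share slide 1 with the controls, at -0.27 and -0.17, and probe brightness by 10000 random sets matched on level, 0% of which were as low (the lowest reached -0.13 and -0.10). A lower copy number of the whole chromosome could not be decided from stretches of 10 Mb. It would place all 8 below all genes in both comparisons, and 6 were. The highest, at 0.19 (SE 0.26) with wild-type ERG, lay within its spread of 0. No DNA was measured, so copy number, clonal differences between lines and regulation by ERG stay open.

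Mitosis and immediate early genes were lower with wild-type ERG than with the mutant. Each slide holds 1 array of each form, so an additive slide difference cancels and the shares per slide could not test it. They show the shift on both slides: 100% of 20 mitosis genes lay below the median of all genes on each, and at least 92.3% of 13 immediate early genes did. A shift of a whole array's scale cannot change such shares either. Quantile normalization, normexp and the authors' matrix gave the same lowest shares, which argues against the choice among these scalings for both lists. The size of the immediate early shift stays uncertain, since its median of -0.70 relative to all genes on slide 1 had a bootstrap standard error of 0.83. The DNA replication list moved in the same direction, by 21.3% (SE 7.41) of the mitosis shift (-0.21 against -0.99). This share cannot decide on fewer cycling cells, since how far such a change lowers each list was not measured. The ERG form, the amount of ERG, fewer cycling cells, growth state at harvest and differences between the cell lines stay open. ERG transcript was lower with wild-type ERG than with the mutant (log2 -3.34 ± 0.39), so its amount cannot be separated from the form. All list calls were lost with an estimated correlation.

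More genes were called with wild-type ERG (1869) than with the mutant (267). A higher amount of ERG transcript is argued against by the ERG probe, which was lower with wild-type ERG (-3.34 ± 0.39), although protein may differ from transcript and the files do not say whether the probe lies in the transfected cDNA. A mutant replicate close to control cannot be told apart from a weaker effect of the mutant: over all 22231 genes the mutant array of slide 2 lay nearer to control than the wild-type array of the same slide for 66.9% of genes (66.4% for the pair on slide 1), but wild-type replicate 1 of slide 1 lay farther than it for only 47.8%. The first principal component, with 65.4% of the variance, placed mutant replicate 1 (62.0) with the controls (57.4 and 70.8). It placed mutant replicate 2 (-34.6) towards wild-type ERG (-54.0 and -102). The second, with 14.7%, placed both mutant replicates (-46.9 and -39.6) apart from the controls (35.8 and 22.2), with wild-type ERG at 17.1 and 11.4. Mutant replicate 1 correlated more with the controls (0.983 and 0.986) than with mutant replicate 2 (0.976). That replicate shares slide 1 with both controls, and slide 2 holds no control. Array intensity followed the first component too: its 75th percentile was 590 and 419 with wild-type ERG and 510 on mutant replicate 2. It was 722 on mutant replicate 1 and 832 and 790 in control. The component values, the correlations and the 47.8% therefore cannot separate slide or array intensity from closeness to control. Loss of function at position 362 and differences between the lines stay open and were not tested.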

How the results depend on the processing

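Crossed replicate numbers and quantile normalization combined with the slide block or a stricter filter were added after seeing the data. Of 148 named-gene results, 3466 alternative values kept their side and direction in 2376 cases, lost the call in 1040, gained it in 40 and changed sign in 10. Of 22 list calls, 264 alternatives kept 215 and lost 49, and 0 changed sign. Only 54.7% to 64.1% of probes per array were well above background, which limits some folds to bounds. With normexp (offset 50) folds shrank. The fitted folds of the 10, 13 and 9 called genes with a bound that were named for each of the 3 comparisons all lay below it. ALDH1A1 and IGFBP5, named for the overlap, were not among the 10 checked with wild-type ERG. The median absolute log2 fold change of called genes fell from 1.496, 2.067 and 2.099 to 0.957, 1.236 and 1.046.

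For the 1869 genes of wild-type ERG against control, median scaling gave 3922, no background filter 737, slide as a fixed block 3130, slide as a random block 4603, slide 1 alone 3024, only the groups compared 4505, adjusted p under 0.1 4421, crossed numbers 3628 and quantile normalization with the slide block 3059; leaving out 1 array gave 0 to 4505. For the 267 of mutant ERG against control, quantile normalization gave 170, median scaling 485, no filter 0 (2948 at unadjusted p under 0.05), the random block 992, slide 1 alone 0 (5970), only the groups compared 0 (2879) and adjusted p under 0.1 629; leaving out 1 array gave 0 to 168. For the 260 between the 2 forms, normexp gave 136, median scaling 899, no filter 2, the fixed block 2083, the random block 2739, slide 1 alone 0 (8770), only the groups compared 1, adjusted p under 0.1 968, the authors' matrix 477, crossed numbers 415 and quantile normalization with the slide block 2179; leaving out 1 array gave 0 to 1156. In place of 214 shared genes, quantile normalization gave 139, 111 of them the same, and no filter 0. The 22 list calls became 0 with an estimated correlation and 18 to 23 when 1 array was left out. Fewer arrays leave fewer degrees of freedom, and without the filter 36379 genes were tested. Fewer degrees of freedom cannot account for rises such as that to 4505 with only the groups compared. Replicates differed by a median of 0.10 in control, 0.29 with wild-type ERG and 0.41 with the mutant, and the main fit pools these spreads. With only the groups compared, the group means stay the same, while the third group's spread and degree of freedom leave the fit. The rise to 4505 therefore came with a spread estimated without the mutant arrays. The 267 and 260 calls depended on the third group in the fit, since 0 and 1 genes passed without it. Whether its spread or its degree of freedom mattered more there was not tested, nor was the cause of the other changes. Slide 2 alone holds 1 array per ERG group and allows no test.

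Samples share a replicate number by label only. Deviations from group means correlated at 0.59 between replicate 1 of wild-type and mutant ERG, but at -0.13 and -0.23 with control replicate 1. With the replicate number as a block, 1641 genes passed in wild-type ERG against control, 0 in mutant ERG against control (3251 at unadjusted p under 0.05), 89 between the 2 forms, and 0 were shared. Exchanging the control numbers gave 3628, 252 and 415.

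The 10 values that changed sign belong to EZH2, which was not called, and to PDGFRB, PSMB8 and CAV1. EZH2 had -0.0018 (normexp) and -0.58 (median scaling) with wild-type ERG, -0.072 (median scaling) and -0.014 (without mutant replicate 1; 0.18 without replicate 2) with the mutant, and 0.00837 (authors' matrix), 0.079 (without mutant replicate 1; -0.11 without replicate 2) and 0.00921 (without wild-type replicate 2) between the 2 forms. PDGFRB had 0.00939 with wild-type ERG and PSMB8 0.076 with the mutant under normexp, and CAV1 -0.097 between the 2 forms in the authors' matrix. The cause was not tested.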

Other observations

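Further lists differed in single members between wild-type ERG and control without a call by camera. Of 9 mesenchymal genes, VIM and SNAI2 (1.66 ± 0.32) rose and the collagen crosslinking enzyme gene LOX fell (-1.05 ± 0.18), with 4 rising and 3 falling adjusted over the list alone (adjusted p = 0.663). Of 19 epithelial junction genes, OCLN fell (-1.64 ± 0.31), 0 adjusted over the list alone (adjusted p = 0.627). Of 9 neuroendocrine genes, ENO2 rose (1.40 ± 0.23) and DDC fell (-1.99 ± 0.15), 1 and 1 adjusted over the list alone (adjusted p = 0.842). HES1 fell 25.3-fold (-4.66 ± 0.28) among 13 NOTCH genes, with 1 rising and 2 falling adjusted over the list alone (adjusted p = 0.26). Of 18 p53 targets, SPATA18 (1.31 ± 0.15) and ZMAT3 (0.86 ± 0.15) rose, 3 rising and 2 falling adjusted over the list alone (adjusted p = 0.925). Of 16 ribosome biogenesis genes, NOLC1 (1.10 ± 0.21, not past the threshold with slide as a block) and NPM1 (0.76 ± 0.14) rose, 2 adjusted over the list alone (adjusted p = 0.555).

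Of 10 WNT targets, TCF7 rose (1.08 ± 0.21, not past the threshold with slide as a block), 2 rising and 2 falling adjusted over the list alone (adjusted p = 0.925). HSPA4L fell (-1.39 ± 0.25) among 11 heat shock genes and ADM (-1.86 ± 0.15) among 16 hypoxia genes, 1 each also adjusted over the list alone (adjusted p = 0.324 for both lists). PSMB9 fell (-1.13 ± 0.14) among 14 antigen presentation genes, 1 adjusted over the list alone (adjusted p = 0.324). Of 20 DNA replication genes, 0 passed, 0 adjusted over the list alone, with a median of -0.24 (adjusted p = 0.128). Of 6 endothelial genes, ICAM2 (1.53 ± 0.30) and ESAM (1.01 ± 0.18) rose and VWF fell (-1.69 ± 0.19, the same sign at 1 of its 2 probes), 2 rising and 2 falling adjusted over the list alone (adjusted p = 0.925). Of 5 fibroblast genes, LUM (-2.71 ± 0.39) and PDGFRB (-1.19 ± 0.23, not past the threshold with slide as a block and 0.00939 with normexp) fell, 2 adjusted over the list alone (adjusted p = 0.198). Of 8 leukocyte genes, 0 passed and 1 rose adjusted over the list alone (adjusted p = 0.236). With the mutant, the lists not named elsewhere had camera adjusted p-values between 0.155 and 0.923, with 1 call among them, VWF (-1.59 ± 0.19, the same sign at 1 of its 2 probes). Between the 2 forms, the lists not called had adjusted p-values between 0.0595 (cholesterol synthesis) and 0.915. With slide as a block camera called cholesterol synthesis lower with wild-type ERG (adjusted p = 0.0147 at the preset correlation). Without the block, an estimated correlation gave this list camera adjusted p = 0.879.

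Of the 267 genes called with the mutant, 251 had the same sign with wild-type ERG, and 106 (39.7%) had a larger change there. These values were not tested further.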
